A study of Mus musculus with 30 samples.

How the data were processed

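RNA-seq libraries of mouse thyroid were analysed from a table of read counts per gene. The values are whole-number counts that the authors deposited for the whole series, with no normalization, in 33924 genes. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1, DESeq2 and the mouse build mm9 were used, and the notes give no role or order for them. The library kit was TruSeq RNA, per the labels, which do not state whether strand was kept. Reads of a gene and of an overlapping or antisense gene may therefore be counted together, and genes of near-identical families share reads. The reference genome at hand is of another build, so genes are given by name only, with no coordinates.

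The labels describe 30 samples in 10 groups, and 28 were analysed here. A vehicle and a CKI sample of Braf Arid2 knockout (replicates 1 and 2) were not analysed here, so these groups held 2 libraries, although the fits had been planned on 30. Groups and replicate numbers came from the sample titles. All columns of the table belonged to a sample. Depth was 23879271 to 34400066 counts per library. The 26 pairs of libraries within groups differed by far more than sampling noise (chi-square per degree of freedom 84.5 to 393), so each was kept as its own replicate.

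Genes with too few counts were removed with edgeR's filterByExpr, which left 19016. Library sizes were scaled by TMM, with factors from 0.723 to 1.25. All 28 libraries entered 1 quasi-likelihood fit (edgeR 4.0.16, glmQLFit and glmQLFTest, in R 4.3.3) with a term per group, so that groups shared an estimate of the spread. From it came 12 comparisons: CKI against vehicle in 4 genotypes, each of 3 knockouts against Braf under vehicle, Braf vehicle and Arid1a knockout against wild type, and 3 differences of drug response between a knockout and Braf. The p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The test, the samples, the gene lists, the rule for named genes and the alternatives were set before the data were examined, unless said otherwise.

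The 28 lists covered thyroid differentiation, thyroid hormone accessory, MAPK output, receptor tyrosine kinases, cell cycle, TGF-beta signalling, mesenchymal transition, epithelial, keratinization, SWI/SNF subunits, interferon-stimulated, class I and class II antigen presentation and dissociation stress genes. They also covered markers of leukocytes, T cells, B cells, macrophages, neutrophils, endothelium, fibroblasts, smooth muscle and pericytes, skeletal muscle, adipocytes, parathyroid, C cells, erythroid cells, and cartilage and airway. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of the camera calls given here, those of the MAPK output and interferon lists in the drug response of Braf Smarcb1 knockout and of the interferon list in its difference from Braf also held with an estimated correlation.

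Named genes followed a rule. It took the targeted genes, the 5 largest rises and falls of each comparison of 2 groups and the 5 smallest p of each difference of responses. The rises and falls needed an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and libraries that did not overlap. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes were left out, and some genes that the rule takes are not reported here. Up to 4 called members of each list described were added, and in drug comparisons the 16 thyroid genes and Dusp6, Spry4, Etv4 and Etv5. A gene with 0 counts in a group is given a fold against a floor of 3 counts over that group. With 1 to 3 counts, the ratio has a 95% counting interval. Floors and intervals cover counting error only.

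The thyroid score is the mean log2(CPM + 1) of 16 genes per library, compared by exact permutation. In Braf it was also fitted by a linear model on group and leukocyte level over the 28 libraries. Alternatives were RLE size factors, no filter, DESeq2 1.42.0, fits of only the compared groups, the replicate number as a block, leaving out each library, and pseudocounts and gene sets for the score. Covariates for the leukocyte level, the dissociation stress level without Egr1 and the Y-linked share were chosen after these levels were seen. On simulated counts of 18275 genes, the Braf drug comparison recovered 62% of 4-fold and 2% of 2-fold changes, with 2 false calls. The Braf Arid2 knockout drug comparison recovered 25% and 1%, and the difference in response with Smarcb1 loss 22% and 1%.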

Results

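RNA-seq read counts per gene were analysed for mouse thyroid in 10 groups. Braf V600E is an activating mutation of the kinase Braf, which drives MAPK signalling. Mice carried it alone or with loss of Arid1a, Arid2 or Smarcb1, which encode subunits of the SWI/SNF chromatin remodelling complex. Each of these 4 genotypes received vehicle or CKI, the labels' name for the MEK inhibitor CH5126766, for 8 days and was killed about 2 h after the last dose. Untreated wild-type and Arid1a knockout thyroids were also measured. The series asks how SWI/SNF loss bears on thyroid tumour progression and on the response to treatment meant to restore thyroid differentiation. Each group held 3 libraries, except the 2 Braf Arid2 knockout groups with 2 each, for 28 libraries in all. The 10 most abundant genes took 6.48% to 21.6% of the counts of a library. Levels are given in CPM, counts scaled to a common library size after TMM, as mean ± SD over the libraries of a group. Log2 fold changes come with their standard error (SE) and a Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test, and medians of gene lists are of log2 fold changes. A list's camera p compares it with all other genes. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries only.

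The targeted genes were read first. Smarcb1 stood at 2.28, 10.03 and 17.9 CPM in the vehicle libraries of Braf Smarcb1 knockout and at 18.1, 47.4 and 11.9 CPM in its CKI libraries. Braf vehicle libraries held 56.97 to 131 CPM, so Smarcb1 fell in the knockout under vehicle (log2 fold change -3.26, SE 0.62, adjusted p = 0.000592). Arid1a did not pass the test in Braf Arid1a knockout (11.98 to 15.9 CPM under vehicle and 19.00 to 29.3 CPM with CKI, against 11.6 to 30.9 CPM in Braf vehicle; log2 fold change under vehicle -0.60, adjusted p = 0.404). In the untreated libraries labelled Arid1a knockout it ran from 21.8 to 27.3 CPM against 27.9 to 39.8 CPM in wild type (log2 fold change -0.47, adjusted p = 0.473). Arid2 measured 15.53 to 37.5 CPM in Braf Arid2 knockout under vehicle and 20.6 to 27.7 CPM with CKI, against 7.03 to 19.7 CPM in Braf vehicle (log2 fold change under vehicle 0.87, adjusted p = 0.189). Counts over a whole gene also take in reads outside a deleted part, so Arid1a and Arid2 counts do not check those labels. Smarcb1 was also lower in the libraries labelled Arid1a knockout than in wild type, at 22.3, 62.5 and 15.1 CPM against 74.8 to 152 CPM (log2 fold change -1.76, SE 0.58, adjusted p = 0.0373).

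Vehicle-treated Braf thyroids were compared with untreated wild-type thyroids, so 8 days of vehicle dosing went with the mutation. Genes of thyroid hormone production were far lower with Braf. Tg, which encodes thyroglobulin, went from 104600 ± 48520 to 417 ± 413 CPM (log2 fold change -7.97, SE 0.87, adjusted p = 2.20e-06). The deiodinase Dio1 went from 1215 ± 394 to 3.01 ± 2.297 CPM and Slc5a5, the sodium iodide symporter, from 156 ± 109 to 1.21 ± 1.78 CPM. In the thyroid differentiation list 2 rose and 11 fell of 16, or 2 up and 12 down adjusted over the list alone (median -2.76, camera adjusted p = 7.37e-08, adjusted p = 0.0911 with an estimated correlation). One gene of this list that rose was Slc26a4, the anion exchanger pendrin, at 0 counts in wild type and 0.563 ± 0.4996 CPM with Braf, at least 16.4-fold higher. Among thyroid hormone accessory genes 6 fell of 9, or 6 down adjusted over the list alone (median -3.07, camera adjusted p = 1.48e-05, adjusted p = 0.0969 with an estimated correlation). They included the oxidase maturation factor Duoxa2 (1.598 ± 0.162 against 73.98 ± 19.7 CPM), the cadherin Cdh16 (41.1 ± 8.34 against 1124 ± 276 CPM) and the iodotyrosine deiodinase Iyd (183 ± 33.4 against 2236 ± 227 CPM).

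MAPK output genes moved the other way, and 7 rose of 19, or 7 up adjusted over the list alone (median 1.01, camera adjusted p = 2.19e-05, adjusted p = 0.0911 with an estimated correlation). The ETS factor Etv4 went from 0.555 ± 0.728 to 29.8 ± 2.42 CPM (log2 fold change 5.74, adjusted p = 9.61e-06). In the TGF-beta signalling list 7 rose of 13, or 9 up and 1 down adjusted over the list alone (median 1.48, camera adjusted p = 6.49e-05, adjusted p = 0.0911 with an estimated correlation). In the mesenchymal transition list 6 rose of 15, or 8 up adjusted over the list alone (median 1.30, camera adjusted p = 5.17e-05, adjusted p = 0.206 with an estimated correlation), among them Fn1, encoding fibronectin (1806 ± 1669 against 37.5 ± 12.2 CPM). Keratinization genes split, and 3 rose and 1 fell of 12, or 3 up and 1 down adjusted over the list alone (median 2.06, camera adjusted p = 0.0221, adjusted p = 0.446 with an estimated correlation). Ivl rose to 51.1 ± 9.11 against 0.976 ± 0.583 CPM, while Krt5 fell to 5.47 ± 1.803 against 35.6 ± 33.4 CPM. Of the cell cycle genes 4 rose of 22, or 4 up adjusted over the list alone (median 1.57, camera adjusted p = 0.000163, adjusted p = 0.503 with an estimated correlation). Without wild-type library 1 the MAPK output and cell cycle medians were 0.65 and 2.53. The keratinization call was lost without that library (camera adjusted p = 0.0812), without Braf vehicle library 2 (median 1.28, camera adjusted p = 0.0514) and with the leukocyte level as a covariate (1.75, camera adjusted p = 0.0696), where the mesenchymal median was 0.85.

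Markers of other cell types differed as well. Endothelial markers were lower, and 9 fell of 10, or 9 down adjusted over the list alone (median -2.56, camera adjusted p = 1.48e-05, adjusted p = 0.206 with an estimated correlation). Fibroblast markers were higher, and 7 rose of 10, or 7 up adjusted over the list alone (median 2.90, camera adjusted p = 0.00351, adjusted p = 0.508 with an estimated correlation). Their level differed widely between Braf vehicle libraries, from 156 to 11560 CPM for Col3a1, and the list's call was lost without library 4 (median 1.503, camera adjusted p = 0.133) and with the leukocyte level as a covariate (0.83, camera adjusted p = 0.442). Parathyroid and C cell markers were far lower. For parathyroid markers 3 fell of 4, or 4 down adjusted over the list alone (median -6.93, camera adjusted p = 0.000358, adjusted p = 0.0911 with an estimated correlation), and parathyroid hormone, Pth, was at 31.2 ± 11.8 against 3931 ± 2083 CPM. For C cell markers 1 rose and 5 fell of 6, or 1 up and 5 down adjusted over the list alone (median -7.02, camera adjusted p = 0.000422, adjusted p = 0.0911 with an estimated correlation), a median of -6.11 with 1 member that had 0 counts in Braf vehicle at its bound. Calca, which encodes calcitonin, was at 26.4 ± 35.6 against 16340 ± 12190 CPM. Leukocyte markers rose, and 4 rose of 7, or 6 up adjusted over the list alone (median 1.86, camera adjusted p = 0.00243, adjusted p = 0.4701 with an estimated correlation).

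The largest rises among all genes were Prss2 (127 CPM, at least 3700-fold), the mast cell protease Mcpt1 (126 CPM, at least 3660-fold), Sftpa1, a surfactant protein (46230 ± 20440 against 4.54 ± 2.22 CPM), the keratin Krt20 (727 ± 323 against 0.0697 ± 0.03800 CPM) and the basophil protease Mcpt8 (2152 ± 2000 against 0.237 ± 0.192 CPM). Prss2 and Mcpt1 had 0 counts in wild type, so their folds are against a floor of 3 counts over that group. The largest falls were Npas4, Serpina3j, Sst and Cckar, at 0 counts in Braf vehicle and at least 505-fold, 390-fold, 335-fold and 292-fold lower, and Chgb, with 1 count there, 4290-fold lower (counting interval 770 to 170000). Genes of close-copy families, such as Mcpt1, Mcpt8, Prss2, Serpina3j and Krt20, share reads with their relatives and are uncertain to that extent. In all 3795 of 19016 genes passed the threshold, 1871 higher and 1924 lower. Krt5 and Col3a1 lost the call without at least 1 library. Without wild-type library 2 the count was 2359, and with the leukocyte marker level as a covariate, chosen after that level was seen, 2409.

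Per the labels, wild-type, Arid2 and Smarcb1 thyroids were flash frozen in 1 text and YFP-positive cells were sorted from dissociated glands in another, and both texts stand on all samples. The labels therefore leave open whether preparation differed between Braf and wild type, and likewise for Arid1a knockout against wild type and for Arid2 or Smarcb1 knockout against Braf.

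The MEK inhibitor was then compared with vehicle within Braf thyroids. Thyroid genes rose. Slc5a5 went from 1.21 ± 1.78 to 321 ± 247 CPM (log2 fold change 8.03, SE 1.36, adjusted p = 0.00132) and Tg from 417 ± 413 to 12820 ± 6285 CPM (log2 fold change 4.94, adjusted p = 0.000523). The thyrotropin receptor gene Tshr went from 15.9 ± 1.48 to 412 ± 200 CPM, Dio1 from 3.01 ± 2.297 to 89.96 ± 48.4 CPM and the transcription factor gene Pax8 from 207 ± 12.8 to 814 ± 199 CPM. Of the thyroid differentiation genes 10 rose of 16, or 11 up and 1 down adjusted over the list alone (median 2.19, camera adjusted p = 1.89e-11, adjusted p = 0.0723 with an estimated correlation). Foxe1, Slc26a4, Nkx2-1 and Thra also rose, with log2 fold changes of 3.16, 3.05, 1.59 and 0.999. Duox2, Duox1, Thrb, Slc5a8, Glis3 and Dio2 did not pass (-2.18 to 2.404). Of the accessory genes 6 rose of 9, or 6 up adjusted over the list alone (median 2.44, camera adjusted p = 1.95e-05, adjusted p = 0.229 with an estimated correlation): Duoxa2 went from 1.598 ± 0.162 to 64.6 ± 27.1 CPM and Iyd from 183 ± 33.4 to 1272 ± 104 CPM. The thyroid score, the mean log2(CPM + 1) of the 16 listed genes, was 5.23 ± 0.30 with CKI and 2.80 ± 0.51 with vehicle (difference 2.43). All CKI libraries lay above all vehicle libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Wild-type thyroids scored 5.91 ± 0.30.

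MAPK output genes did not move together in Braf thyroids. On this list 2 rose and 3 fell of 19, or 2 up and 3 down adjusted over the list alone (median 0.34, camera adjusted p = 0.742). Etv4 fell from 29.8 ± 2.42 to 2.55 ± 0.529 CPM, while Egr1 rose from 321 ± 183 to 1817 ± 939 CPM and Phlda1 from 27.1 ± 10.96 to 121 ± 39.6 CPM. Dusp6 (0.28, adjusted p = 0.7302), Spry4 (1.15, adjusted p = 0.0876) and Etv5 (-0.84, adjusted p = 0.226) did not pass, as log2 fold changes. Immediate early genes of the dissociation stress list were higher, and 6 rose of 13, or 6 up adjusted over the list alone (median 1.61, camera adjusted p = 0.000161, adjusted p = 0.405 with an estimated correlation). Jun went from 138 ± 83.9 to 1431 ± 880.3 CPM and Ier2 from 114 ± 82.6 to 1292 ± 686 CPM. Egr1 stands on both lists. The mean log2(CPM + 1) of the stress list was 9.94 ± 0.37 with CKI and 8.24 ± 0.68 with vehicle, and its call was lost with the leukocyte level as a covariate (median 0.67, camera adjusted p = 0.231).

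Leukocyte markers fell, and 7 fell of 7, or 7 down adjusted over the list alone (median -2.93, camera adjusted p = 6.43e-08, adjusted p = 0.229 with an estimated correlation). Cd53 went from 133 ± 18.5 to 15.2 ± 5.23 CPM. The mean log2(CPM + 1) of this list was 3.93 ± 0.52 with CKI and 6.69 ± 0.29 with vehicle. Macrophage markers followed, and 5 fell of 9, or 9 down adjusted over the list alone (median -2.12, camera adjusted p = 8.11e-07, adjusted p = 0.351 with an estimated correlation), with Cd14 (60.6 ± 35.9 against 389 ± 55.6 CPM) and the complement genes C1qa and C1qb. In the class II antigen presentation list 4 fell of 7, or 5 down adjusted over the list alone (median -1.30, camera adjusted p = 0.000305, adjusted p = 0.405 with an estimated correlation). Examples were H2-Aa (147 ± 78.2 against 616 ± 181 CPM) and H2-Eb1 (114 ± 65.3 against 418 ± 111 CPM). With the leukocyte level as a covariate the macrophage and class II calls were lost (medians 0.56 and 0.10, camera adjusted p = 0.811 and 0.965), and H2-Aa, H2-Eb1, C1qa and C1qb had positive log2 fold changes that did not pass. The leukocyte and thyroid accessory medians were -1.89 and 1.25 with the stress level as a covariate. Class I genes were not called as a list, and 2 rose of 9, or 4 up adjusted over the list alone (median 0.53, camera adjusted p = 0.0999). These were H2-D1 (2978 ± 451 against 1035 ± 369.9 CPM) and H2-K1 (1556 ± 122 against 656 ± 232 CPM). The H2 genes share reads with close relatives.

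Slc5a5 was among the 5 largest rises, with Ppp1r1b, a phosphatase inhibitor (474 ± 215 against 7.197 ± 1.41 CPM), and the anion transporter Slc26a10 (197 ± 120 against 3.28 ± 0.938 CPM). Among the 5 largest falls were Cyp24a1, which inactivates vitamin D (0.151 ± 0.197 against 11.2 ± 9.61 CPM), Mcpt8 (36.9 ± 26.99 against 2152 ± 2000 CPM) and Spp1, encoding osteopontin (746 ± 271 against 39210 ± 22210 CPM). In all 2466 genes passed, 1513 higher and 953 lower with CKI. Slc26a4, Nkx2-1, Thra, Egr1, Phlda1, Jun, Ier2, C1qa, C1qb, H2-Aa, H2-Eb1, H2-D1, H2-K1 and Cyp24a1 lost the call without at least 1 library. Without Braf vehicle library 2 or 4 the count was 726 or 1353, without CKI library 1 or 4 it was 806 or 899, and 1367 when only these 6 libraries were fitted. Most calls became lower without vehicle library 4 (575 of 1353 higher). With the leukocyte or the dissociation stress level as a covariate, both chosen after the levels were seen, it was 99 or 117, and the thyroid differentiation list kept its camera call in each of these refits at the preset correlation (adjusted p = 0.0723 with an estimated correlation in the fit of all libraries).

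In Braf Arid1a knockout thyroids, thyroid genes were also higher with CKI. Tg went from 580.1 ± 336 to 26210 ± 4723 CPM (log2 fold change 5.50, SE 0.78, adjusted p = 0.000509), Slc5a5 from 1.54 ± 0.784 to 205 ± 291 CPM and Dio1 from 1.88 ± 0.974 to 134 ± 88.1 CPM. On the thyroid differentiation list 8 rose of 16, or 11 up adjusted over the list alone (median 1.77, camera adjusted p = 9.58e-12, adjusted p = 0.0836 with an estimated correlation). Duox2, Pax8, Foxe1 and Tshr also rose, with log2 fold changes of 4.47, 2.16, 1.97 and 1.57. Slc26a4, Duox1, Nkx2-1, Glis3, Thra, Slc5a8, Thrb and Dio2 did not pass (0.18 to 2.52). Of the accessory genes 4 rose of 9, or 6 up adjusted over the list alone (median 2.15, camera adjusted p = 4.50e-07, adjusted p = 0.0947 with an estimated correlation), with Cdh16 going from 26.9 ± 4.16 to 749 ± 330.3 CPM and Duoxa2 from 1.38 ± 1.17 to 36.4 ± 1.900 CPM. The thyroid score was 5.28 ± 0.46 with CKI and 3.26 ± 0.20 with vehicle (difference 2.02, exact permutation p = 0.1, the smallest possible).

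MAPK output genes were lower, and 5 fell of 19, or 1 up and 7 down adjusted over the list alone (median -0.75, camera adjusted p = 1.40e-05, adjusted p = 0.0947 with an estimated correlation). Etv5 fell from 75.4 ± 23.6 to 8.44 ± 5.25 CPM (log2 fold change -3.16, adjusted p = 0.00101), Etv4 from 28.6 ± 11.9 to 6.503 ± 3.11 CPM and Ccnd1, encoding cyclin D1, from 626 ± 168 to 157 ± 21.4 CPM. Dusp6 (-0.96, adjusted p = 0.222) and Spry4 (-1.41, adjusted p = 0.0686) did not pass. The list's median was -0.50 or -1.32 without CKI library 2 or 5, and -1.23 or -1.13 with the leukocyte or stress level as a covariate. In the receptor tyrosine kinase list 2 rose of 11, or 4 up adjusted over the list alone (median 0.81, camera adjusted p = 0.00917, adjusted p = 0.366 with an estimated correlation). These were Egfr (27.6 ± 16.5 against 5.91 ± 0.607 CPM) and Fgfr2 (42.3 ± 18.1 against 12.8 ± 4.07 CPM). Leukocyte markers were lower, and 1 fell of 7, or 6 down adjusted over the list alone (median -1.96, camera adjusted p = 3.80e-06, adjusted p = 0.231 with an estimated correlation). Cd53 was at 18.4 ± 14.4 against 92.6 ± 33.6 CPM. In the class II list 4 fell of 7, or 6 down adjusted over the list alone (median -1.53, camera adjusted p = 5.81e-06, adjusted p = 0.231 with an estimated correlation). Cd74 was at 841 ± 173 against 2768 ± 1590 CPM. The receptor and class II calls were lost with the leukocyte level as a covariate (medians 0.51 and -0.41), and the receptor call also without CKI library 5 (0.32, camera adjusted p = 0.06001).

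Slc26a10 (136 ± 62.3 against 2.98 ± 0.774 CPM) and the peptide hormone gene Adm2 (7.73 ± 4.43 against 0.123 ± 0.121 CPM) were among the 5 largest rises, beside Slc5a5, Dio1 and Tg. Largest among the falls was Bpifb9a, with 0 counts in CKI libraries and at least 357-fold lower, though its vehicle level rested on uneven libraries (12.8 ± 21.8 CPM). In all 858 genes passed, 477 higher and 381 lower. Among called genes named for this comparison, only Tg, Slc5a5, Dio1, Pax8, Cdh16, Duoxa2, Etv5, Slc26a10 and Adm2 kept the call without each library in turn. The count was 377, 403 or 256 without vehicle library 1, 2 or 3, and 435 or 378 without CKI library 2 or 5, and without vehicle library 1 most calls became lower (186 of 377 higher). It was 527 when only these 6 libraries were fitted, and 248 with the leukocyte level as a covariate, chosen after it was seen.

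In Braf Arid2 knockout thyroids each arm held 2 libraries. Tg went from 541 ± 198 to 49360 ± 18440 CPM with CKI (log2 fold change 6.51, SE 1.004, adjusted p = 0.00126), Tshr from 17.96 ± 2.88 to 403 ± 52.2 CPM and Dio1 from 4.22 ± 1.99 to 235 ± 49.2 CPM. Among thyroid differentiation genes 6 rose of 16, or 6 up and 1 down adjusted over the list alone (median 1.91, camera adjusted p = 1.96e-06, adjusted p = 0.278 with an estimated correlation). Examples were Duox2 and Pax8 (log2 fold changes 6.23 and 2.00). Slc5a5 did not pass (log2 fold change 3.17, adjusted p = 0.188), at 12.6 ± 4.59 CPM with CKI against 321 ± 247 CPM in Braf with CKI. Slc26a4, Dio2, Duox1, Foxe1, Glis3, Slc5a8, Thra, Nkx2-1 and Thrb did not pass either (-3.51 to 2.42). Of the accessory genes 4 rose of 9, or 5 up and 1 down adjusted over the list alone (median 2.01, camera adjusted p = 0.00119, adjusted p = 0.306 with an estimated correlation). Examples were Duoxa2 (98.5 ± 16.9 against 3.15 ± 1.93 CPM) and Slc26a7 (179 ± 40.1 against 10.9 ± 11.2 CPM). The thyroid score was 4.83 ± 0.10 with CKI and 3.05 ± 0.08 with vehicle (difference 1.79, exact permutation p = 0.333, the smallest that 2 against 2 allows).

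In the MAPK output list 1 fell of 19, or 9 down adjusted over the list alone (median -1.003, camera adjusted p = 0.000905, adjusted p = 0.278 with an estimated correlation). This was Spred2 (10.2 ± 1.52 against 37.9 ± 19.8 CPM). Dusp6 (-1.98, adjusted p = 0.0515), Spry4 (-1.53, adjusted p = 0.116), Etv4 (-2.46, adjusted p = 0.0659) and Etv5 (-1.68, adjusted p = 0.0931) had negative log2 fold changes that did not pass. Mesenchymal transition genes were lower, and 2 fell of 15, or 8 down adjusted over the list alone (median -1.93, camera adjusted p = 3.03e-05, adjusted p = 0.278 with an estimated correlation). These were Vim, encoding vimentin (89.3 ± 41.05 against 1170 ± 662 CPM), and Mmp14 (3.800 ± 1.75 against 45.4 ± 28.8 CPM). For leukocyte markers 0 passed the test of 7, or 4 down adjusted over the list alone (median -2.25, camera adjusted p = 0.0005104, adjusted p = 0.329 with an estimated correlation). With the leukocyte level as a covariate the mesenchymal and accessory medians were -1.05 and 3.10.

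The largest rises besides Tg and Duox2 were Tmem35 (359 ± 108 against 2.33 ± 0.622 CPM), Adm2 (23.1 ± 5.47 against 0.184 ± 0.152 CPM) and the gluconeogenic enzyme gene Fbp2 (96.1 ± 44.4 against 1.11 ± 0.123 CPM). Spp1 fell from 45170 ± 633 to 98.4 ± 16.4 CPM, Chi3l3 from 255 ± 156 to 0.202 ± 0.119 CPM and Cyp24a1 from 63.1 ± 6.18 to 0.276 ± 0.3898 CPM. Megf10, with 1 count in CKI libraries, was 291-fold lower (counting interval 51.8 to 11500). In all 640 genes passed, 268 higher and 372 lower. Among called genes named for this comparison, only Tg, Tshr, Tmem35, Adm2, Fbp2 and Spp1 kept the call without each library in turn. The count was 81 or 349 without vehicle library 2 or 4 and 65 or 107 without CKI library 3 or 4, where the lone library left in an arm is taken to vary like the other groups. Without CKI library 3 or 4 most calls became higher (48 of 65 and 87 of 107). The count was 991 with the dissociation stress level as a covariate, chosen after it was seen, and 1651 when only these 4 libraries were fitted.

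Thyroid genes were higher with CKI in Braf Smarcb1 knockout thyroids too. Tg went from 66.6 ± 50.1 to 1666 ± 391.7 CPM (log2 fold change 4.64, SE 0.75, adjusted p = 0.00137), Tshr from 3.31 ± 1.96 to 13.1 ± 3.75 CPM and Pax8 from 77.98 ± 24.1 to 244 ± 32.6 CPM. In the thyroid differentiation list 6 rose of 16, or 8 up adjusted over the list alone (median 0.96, camera adjusted p = 8.52e-08, adjusted p = 0.0925 with an estimated correlation). Its median was 0.57 or 1.61 without vehicle library 1 or 2, and 0.63 with the stress level as a covariate. Examples were Foxe1 and Thra (log2 fold changes 2.60 and 1.41). Slc5a5 was at 28.7 ± 15.4 against 25.9 ± 13.5 CPM (log2 fold change 0.15, adjusted p = 0.959). Dio1 (2.16), Nkx2-1 (1.05), Slc26a4, Duox2, Slc5a8, Thrb, Glis3, Duox1 and Dio2 (-0.05) did not pass. Of the accessory genes 4 rose of 9, or 5 up adjusted over the list alone (median 1.70, camera adjusted p = 3.77e-06, adjusted p = 0.09504 with an estimated correlation), with Cdh16 going from 3.400 ± 2.71 to 46.4 ± 30.4 CPM. The thyroid score was 3.31 ± 0.20 with CKI and 2.12 ± 0.44 with vehicle (difference 1.19, exact permutation p = 0.1, the smallest possible).

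MAPK output genes were lower, and 6 fell of 19, or 1 up and 12 down adjusted over the list alone (median -1.11, camera adjusted p = 1.62e-09, adjusted p = 0.0175 with an estimated correlation). Spry4 went from 174 ± 56.98 to 33.8 ± 13.4 CPM, Etv5 from 67.7 ± 37.9 to 9.001 ± 2.62 CPM, Etv4 from 13.7 ± 5.399 to 2.13 ± 0.838 CPM and Ccnd1 from 1277 ± 597 to 321 ± 54.7 CPM, while Dusp6 did not pass (log2 fold change -1.33, adjusted p = 0.101). Cell cycle genes were lower, and 10 fell of 22, or 22 down adjusted over the list alone (median -2.28, camera adjusted p = 2.08e-17, adjusted p = 0.0925 with an estimated correlation). Ube2c fell from 87.2 ± 49.5 to 7.93 ± 3.32 CPM and Rrm2 from 161 ± 101 to 20.01 ± 6.99 CPM. Interferon-stimulated genes were higher, and 11 rose of 17, or 15 up adjusted over the list alone (median 1.65, camera adjusted p = 2.74e-21, adjusted p = 0.00254 with an estimated correlation). Irf7 went from 46.1 ± 15.2 to 275 ± 132 CPM and Ifit1 from 88.99 ± 26.6 to 464 ± 196 CPM. In the dissociation stress list 1 rose of 13, or 5 up adjusted over the list alone (median 1.47, camera adjusted p = 1.73e-06, adjusted p = 0.201 with an estimated correlation). This was Nr4a1 (513 ± 207 against 174 ± 28.7 CPM). The list's level was 9.53 ± 0.02 with CKI and 8.10 ± 0.50 with vehicle, and with it as a covariate the MAPK output and accessory medians were -1.72 and 0.96.

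The 5 largest rises included Tg, Ppp1r1b (110 ± 99.7 against 3.17 ± 2.49 CPM) and Aox3 (34.4 ± 4.599 against 1.62 ± 0.164 CPM). The 5 largest falls included the proteases Mcpt2, at 0 counts with CKI and at least 212-fold lower, and Mcpt8 (1.64 ± 1.18 against 204 ± 227 CPM), and Lce1g, with 2 counts with CKI and 309-fold lower (counting interval 85.2 to 2560). In all 732 genes passed, 342 higher and 390 lower. Tshr, Foxe1, Thra, Etv4, Ccnd1, Ube2c, Nr4a1, Aox3 and Lce1g lost the call without at least 1 library. The count was 233 or 437 without vehicle library 1 or 2 and 292, 365 or 484 without CKI library 1, 2 or 4. It was 2 when only these 6 libraries were fitted, and 172 with the dissociation stress level as a covariate, chosen after it was seen. Rises became the majority in 9 of 14 alternatives.

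**Figure D1:**
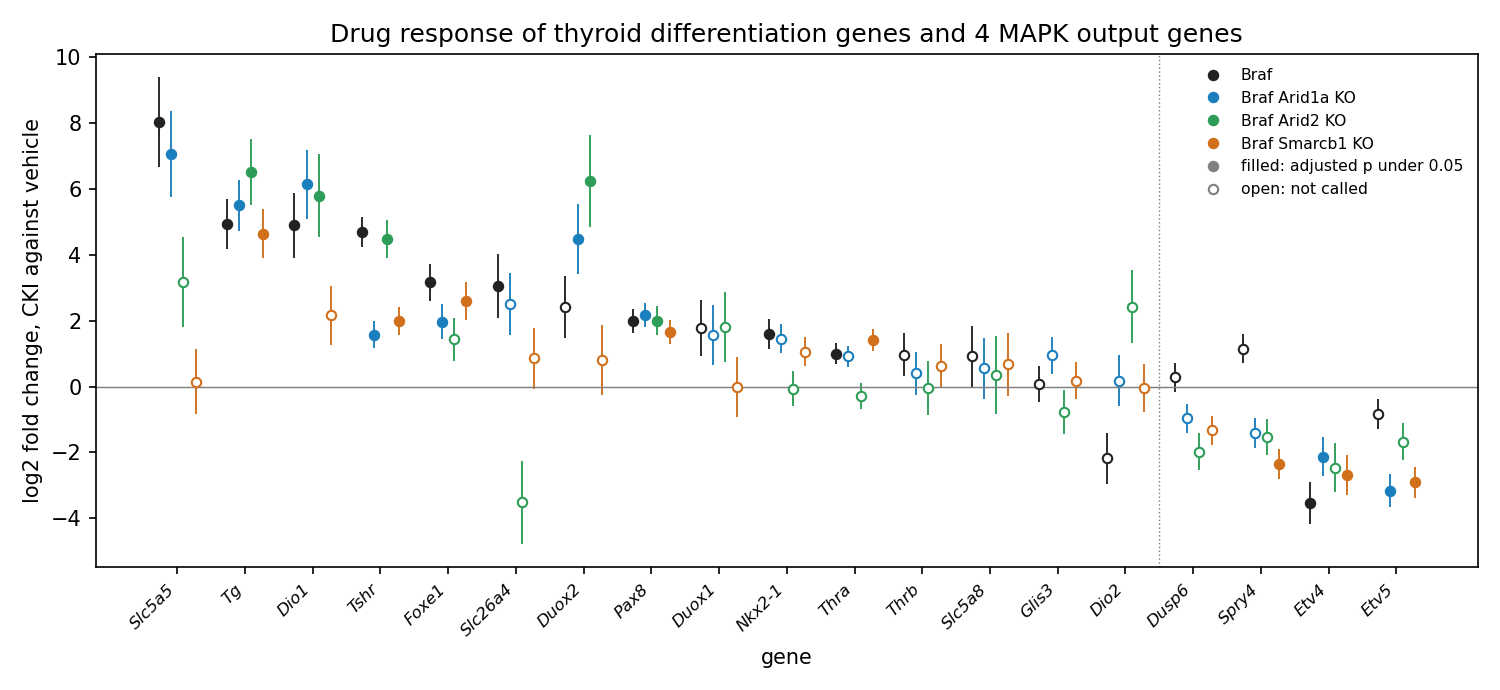
Log2 fold change of CKI against vehicle (points, with 1 SE as bars) for thyroid differentiation genes and 4 MAPK output genes, in each Braf genotype. Filled points have an adjusted p under 0.05; Slc5a5 stands at 8.03 in Braf and at 0.15 in Braf Smarcb1 knockout.

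**Figure D2:**
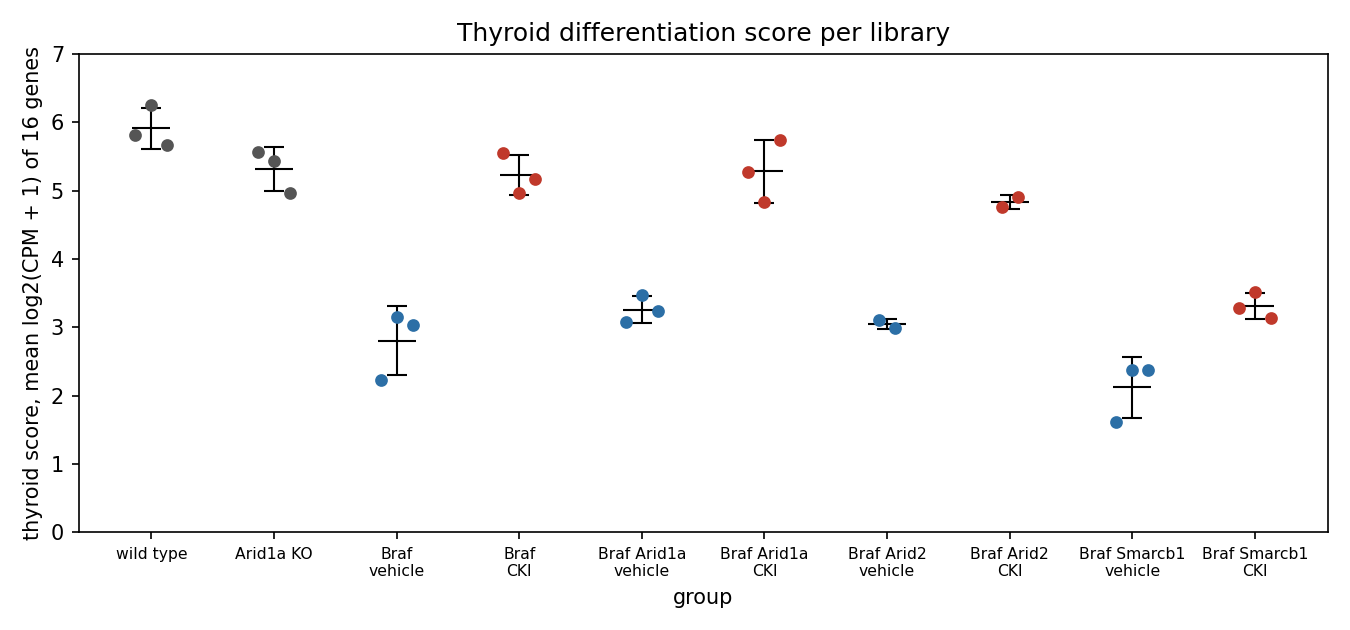
Thyroid score, the mean log2(CPM + 1) of 16 genes, per library (points) and as group mean with SD (lines), for the 10 groups. CKI libraries lie above the vehicle libraries of their genotype, with means of 5.23 in Braf and 3.31 in Braf Smarcb1 knockout.

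Over the 4 Braf genotypes the thyroid score rose by 1.86 on average with CKI (stratified exact permutation p = 4.17e-05, the smallest that 48000 relabelings can give). Each knockout's response was then set against that of the same Braf libraries. For the score the difference was -0.40 with Arid1a loss, -0.64 with Arid2 loss and -1.24 with Smarcb1 loss. Relabelling genotype within arms gave permutation p = 0.35, 0.17 and 0.02 (adjusted p = 0.35, 0.255 and 0.06), so none passed. Overlaps of drug responses were set against those of independent lists. Braf and Braf Arid1a knockout shared 210 rises (38.0 for independent lists) and 206 falls (19.1). Braf and Braf Arid2 knockout shared 114 rises (21.3) and 122 falls (18.6), and Braf and Braf Smarcb1 knockout 119 rises (27.2) and 138 falls (19.5). All 4 responses shared 30 rises, among them Tg, Tshr, Pax8, Iyd, Duoxa2, Cdh16 and Slc26a7, and 13 falls, among them Spp1, Mcpt8 and Chi3l3, where independent lists would share 0.00962 and 0.00766.

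With Arid1a loss no gene differed in its response (0 genes in edgeR, 2018 at an unadjusted p under 0.05, 172 in DESeq2). The 5 smallest p belonged to Ppara, Tshr, Fbp2, Dhrs3 and Phf7, each with an adjusted p of 0.106. Tshr started from 185 ± 67.9 CPM under vehicle with Arid1a loss and from 15.9 ± 1.48 CPM in Braf, and its difference in response was -3.12 (SE 0.58). Without CKI library 5 of Braf Arid1a knockout 275 genes passed, and 1 passed without its vehicle library 2, CKI library 2 or CKI library 4.

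With Arid2 loss 1647 genes differed, 280 more positive and 1367 more negative than in Braf. The 5 smallest p belonged to Tmem135, Zfp692, H2afy2, Schip1 and Fez2, which were all higher with CKI in Braf and lower in Braf Arid2 knockout. Fez2, for example, measured 24.5 ± 10.7 and 84.5 ± 25.99 CPM in Braf and 96.1 ± 1.73 and 26.1 ± 1.22 CPM with Arid2 loss (difference -3.67, adjusted p = 0.0123). Among MAPK output genes Dusp6 (-2.26, adjusted p = 0.0484), Spry4 (-2.67, adjusted p = 0.0231), Phlda1 (-2.70, adjusted p = 0.0345) and Spred2 (-2.45, adjusted p = 0.0165) had more negative responses. The stress genes Jun, Ier2 and Junb did too (-4.48, -4.93 and -4.08). Of the thyroid genes Slc26a4 (-6.56, adjusted p = 0.0192) and Dio2 (4.61, adjusted p = 0.03798) passed at levels under 5 CPM, and Slc5a5 did not (-4.86, adjusted p = 0.0799). Each called gene named in this comparison lost the call without at least 1 of its libraries. The count was 0 or 1 without Braf Arid2 knockout CKI library 3 or 4, 310 without its vehicle library 2, 717 or 1000 without Braf CKI library 1 or 4, and 0 with the dissociation stress level as a covariate.

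With Smarcb1 loss 58 genes differed, 21 more positive and 37 more negative, against 268 in DESeq2. The response of Slc5a5 differed by -7.88 (log2, SE 1.59, adjusted p = 0.0311), from 25.9 ± 13.5 to 28.7 ± 15.4 CPM with Smarcb1 loss. Part of that difference was its higher vehicle level than in Braf. Tshr's response was also more negative (-2.70, adjusted p = 0.0448). Of the thyroid differentiation genes 2 fell of 16, or 2 down adjusted over the list alone in the difference (median -0.55, camera adjusted p = 0.00316, adjusted p = 0.537 with an estimated correlation). Its camera adjusted p was 0.087 without Braf vehicle library 2 and 0.0674 without Braf Smarcb1 knockout vehicle library 3, and its median -1.25 or -0.87 without Braf vehicle library 4 or 5 and -0.98 or -1.17 without Smarcb1 knockout vehicle library 1 or CKI library 2. Spry4 (-3.51) and Cdc20 (-4.06) were more negative, and Ifit3 (3.01), Usp18 (2.88), Ifit1 (2.83) and Irf7 (2.79) more positive. The interferon list was higher in the difference, and 7 rose of 17, or 16 up adjusted over the list alone (median 2.02, camera adjusted p = 5.04e-27, adjusted p = 0.000724 with an estimated correlation). The 5 smallest p belonged to Elovl6 (-3.39, adjusted p = 0.00103), Bcl2 (-3.79, adjusted p = 0.004500), Slc26a10 (-4.39, adjusted p = 0.00739), Gstm1 (2.55, adjusted p = 0.00921) and Slc38a1 (-2.18, adjusted p = 0.009805), and these 5 and Usp18 kept their calls without each library in turn. Left-out libraries moved the count to 35, 28 or 38 (Braf vehicle 2, 4 or 5), 23, 33 or 34 (Braf CKI 1, 4 or 5), 30 (Smarcb1 knockout vehicle 2) and 20 or 19 (Smarcb1 knockout CKI 1 or 2). It was 5 when only the 12 libraries compared were fitted and 10 with the leukocyte level as a covariate.

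Knockouts were next compared with Braf alone under vehicle, and the 3 comparisons used the same 3 Braf vehicle libraries. With Arid1a loss, stromal genes were lower. In the fibroblast list 9 fell of 10, or 9 down adjusted over the list alone (median -3.76, camera adjusted p = 1.97e-07, adjusted p = 0.223 with an estimated correlation). Lum, encoding lumican, was at 29.99 ± 8.88 against 714 ± 704 CPM. Smooth muscle and pericyte markers followed, and 5 fell of 7, or 5 down adjusted over the list alone (median -3.55, camera adjusted p = 1.43e-05, adjusted p = 0.198 with an estimated correlation). Endothelial markers were lower as well, and 5 fell of 10, or 8 down adjusted over the list alone (median -2.87, camera adjusted p = 5.66e-05, adjusted p = 0.468 with an estimated correlation). In the mesenchymal transition list 1 rose and 8 fell of 15, or 1 up and 12 down adjusted over the list alone (median -2.28, camera adjusted p = 2.35e-07, adjusted p = 0.198 with an estimated correlation). These stromal levels differed widely between the Braf vehicle libraries, from 107 to 1485 CPM for Lum, and the fibroblast median was -2.48 without library 4. The dissociation stress level was 9.14 ± 0.30 against 8.24 ± 0.68. Interferon-stimulated genes were lower, and 4 fell of 17, or 7 down adjusted over the list alone (median -0.79, camera adjusted p = 4.19e-05, adjusted p = 0.223 with an estimated correlation).

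On the thyroid differentiation list 2 rose of 16, or 2 up and 1 down adjusted over the list alone (median 0.22, camera adjusted p = 0.162). Tshr was at 185 ± 67.9 against 15.9 ± 1.48 CPM (log2 fold change 3.54, SE 0.45, adjusted p = 6.90e-05). The thyroid score differed by 0.46 (exact permutation p = 0.2). Among the 5 largest rises were H2-Bl, with 2 counts in Braf vehicle and 372-fold higher (counting interval 103 to 3080), the fibrinogen chain gene Fgg (74.3 ± 30.1 against 0.323 ± 0.559 CPM), Bpifb9a (12.8 ± 21.8 against 0.0503 ± 0.0437 CPM) and Grp, encoding gastrin-releasing peptide (58.8 ± 23.9 against 0.514 ± 0.365 CPM). The largest falls were Adamtsl2 (0.0634 ± 0.1099 against 37.2 ± 11.1 CPM), Mmp10, Cxcl9, C1qtnf9 and Mcpt1, with log2 fold changes from -9.04 to -6.19. In all 1818 genes passed, 808 higher and 1010 lower. Bpifb9a and Cxcl9 lost the call without at least 1 library. The count was 948 without Braf vehicle library 4 and 737, 1078 or 1012 (507 of them higher) without Arid1a knockout library 1, 2 or 3. It was 829 when only these 6 libraries were fitted.

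With Arid2 loss, 2 libraries were compared with 3. Interferon-stimulated genes were lower, and 5 fell of 17, or 12 down adjusted over the list alone (median -1.24, camera adjusted p = 4.27e-10, adjusted p = 0.0857 with an estimated correlation). Oas1a was at 4.23 ± 0.311 against 28.4 ± 6.400 CPM (log2 fold change -2.75, SE 0.36, adjusted p = 0.000344) and Ifit1 at 4.998 ± 2.69 against 20.9 ± 8.47 CPM. Fibroblast markers were lower, and 4 fell of 10, or 10 down adjusted over the list alone (median -3.56, camera adjusted p = 6.01e-07, adjusted p = 0.477 with an estimated correlation). Dcn, encoding decorin, was at 138 ± 0.426 against 1556 ± 1247 CPM. Leukocyte and macrophage markers were lower as lists, though 0 of 7 and 0 of 9 passed edgeR's test, also adjusted over the list alone (medians -1.25 and -1.19, camera adjusted p = 0.0213 and 0.0125, both adjusted p = 0.665 with an estimated correlation). Their levels were 5.57 ± 0.11 against 6.69 ± 0.29 and 6.26 ± 0.09 against 7.42 ± 0.41, and that of the dissociation stress list 9.17 ± 0.05 against 8.24 ± 0.68. In the MAPK output list 1 rose of 19, or 2 up adjusted over the list alone (median 0.87, camera adjusted p = 0.0213, adjusted p = 0.548 with an estimated correlation). This was Phlda1 (101 ± 9.76 against 27.1 ± 10.96 CPM). The MAPK output call was lost without Braf vehicle library 4 (median 0.61) or Arid2 knockout library 2 (0.56) and with the leukocyte (0.63) or stress level (0.38) as a covariate. The leukocyte call was lost without library 4 of Braf (-0.91) or of the knockout (-1.02) and with the stress level (-0.89) and the macrophage call with the leukocyte level (-0.18). The fibroblast median was -2.19 without Braf vehicle library 4. Thyroid genes were not called as a list, and 1 fell of 16, or 1 down adjusted over the list alone (median 0.22, camera adjusted p = 0.4697). This was Dio2 (0.07498 ± 0.00295 against 2.29 ± 2.36 CPM). The thyroid score differed by 0.24 (exact permutation p = 0.9). Among the 5 largest rises were Nefl, with 2 counts in Braf vehicle and 218-fold higher (counting interval 59.8 to 1810), Jph3, with 2 counts and 206-fold higher (56.6 to 1710), and Trim9 (19.4 ± 11.9 against 0.761 ± 0.181 CPM). Psca fell most, with 3 counts in Braf Arid2 knockout and 6350-fold lower (counting interval 2170 to 30800). Ly6d (1.75 ± 0.726 against 120.5 ± 55.9 CPM) and C1qtnf3 (8.29 ± 3.27 against 251 ± 333 CPM) were among the 5 largest falls too. In all 686 genes passed, 443 higher and 243 lower. Among called genes named for this comparison, only Oas1a kept the call without each library in turn. The count was 365 or 54 without Braf vehicle library 2 or 4, 38 or 89 without Arid2 knockout library 2 or 4, and 1 when only these 5 libraries were fitted. Most calls became lower without Braf vehicle library 2 or 4 (121 of 365 and 21 of 54 higher), and the count was 111, 173 or 401 with the leukocyte level, the stress level or the Y-linked share as a covariate, chosen after these were seen.

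With Smarcb1 loss 5433 genes were called, 2736 higher and 2697 lower. Cell cycle genes were higher, and 20 rose of 22, or 21 up adjusted over the list alone (median 2.62, camera adjusted p = 2.13e-08, adjusted p = 0.511 with an estimated correlation). Ccna2, encoding cyclin A2, was at 38.6 ± 20.6 against 0.812 ± 0.484 CPM (log2 fold change 5.54, SE 0.84, adjusted p = 8.07e-05) and Rrm2 at 161 ± 101 against 8.14 ± 4.03 CPM. Epithelial genes were lower, and 12 fell of 14, or 12 down adjusted over the list alone (median -2.55, camera adjusted p = 5.61e-10, adjusted p = 0.393 with an estimated correlation). Examples were the tight junction gene Cldn4 (37.99 ± 28.4 against 729 ± 339 CPM) and the keratin gene Krt19 (121 ± 111 against 1588 ± 667 CPM). Among thyroid differentiation genes 1 rose and 7 fell of 16, or 1 up and 7 down adjusted over the list alone (median -1.30, camera adjusted p = 0.0111, adjusted p = 0.523 with an estimated correlation). Tg was at 66.6 ± 50.1 against 417 ± 413 CPM, Tshr at 3.31 ± 1.96 against 15.9 ± 1.48 CPM and Glis3 at 2.78 ± 2.42 against 17.5 ± 3.27 CPM, while Slc5a5 was higher, at 25.9 ± 13.5 against 1.21 ± 1.78 CPM (log2 fold change 4.40, adjusted p = 0.00749). The accessory list was lower, and 5 fell of 9, or 7 down adjusted over the list alone (median -2.15, camera adjusted p = 0.000115, adjusted p = 0.393 with an estimated correlation). Cdh16 was at 3.400 ± 2.71 against 41.1 ± 8.34 CPM and Iyd at 23.6 ± 18.3 against 183 ± 33.4 CPM. The thyroid differentiation call was lost without Braf vehicle library 4 or Smarcb1 knockout library 1 (medians -0.91 and -1.075, camera adjusted p = 0.0831 and 0.0936) and with the replicate block (-0.97, camera adjusted p = 0.07). The thyroid score differed by -0.68 (exact permutation p = 0.3).

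MAPK output genes were not called as a list, and 6 rose and 2 fell of 19, or 7 up and 3 down adjusted over the list alone (median 0.39, camera adjusted p = 0.522). Spry4 (174 ± 56.98 against 15.8 ± 7.35 CPM) and Spry1 (62.2 ± 15.9 against 15.3 ± 5.92 CPM) rose and Epha4 (4.46 ± 3.71 against 27.4 ± 4.63 CPM) fell. Interferon-stimulated genes were higher, and 9 rose and 1 fell of 17, or 10 up and 2 down adjusted over the list alone (median 0.97, camera adjusted p = 0.00347, adjusted p = 0.5202 with an estimated correlation). Markers of other cells were lower: for leukocytes 4 fell of 7, or 7 down adjusted over the list alone (median -1.68, camera adjusted p = 0.00473, adjusted p = 0.523 with an estimated correlation), for macrophages 6 fell of 9, or 7 down adjusted over the list alone (median -2.05, camera adjusted p = 0.00219, adjusted p = 0.523 with an estimated correlation), and for fibroblasts 6 fell of 10, or 7 down adjusted over the list alone (median -2.51, camera adjusted p = 0.00787, adjusted p = 0.685 with an estimated correlation). Csf1r, a macrophage receptor gene at 26.2 ± 7.16 against 128 ± 79.7 CPM, had a positive log2 fold change that did not pass with the leukocyte level as a covariate. The macrophage and fibroblast calls were then lost (medians 0.023 and -0.56), the fibroblast call also without Braf vehicle library 4 (-1.17, camera adjusted p = 0.156), and the leukocyte median was -2.63 without Smarcb1 knockout library 3.

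The 5 largest rises had 0 counts in all Braf vehicle libraries. They were Lingo2 (35.6 CPM), Gad1 (31.8 CPM), the LIM homeobox gene Lhx9 (23.3 CPM), Klhl1 (22.1 CPM) and Ng23 (19.0 CPM), at least 862-fold, 771-fold, 565-fold, 535-fold and 461-fold higher. Among the 5 largest falls were Tnmd (0.2198 ± 0.0418 against 27.4 ± 22.9 CPM) and C1qtnf3 (4.16 ± 2.98 against 251 ± 333 CPM). Tg and Csf1r lost the call without at least 1 library. The count was 2335 when only the 6 libraries compared were fitted and 2373 with the leukocyte level as a covariate, chosen after it was seen.

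Untreated thyroids labelled Arid1a knockout were compared with wild type to measure Arid1a loss without mutant Braf. Immune genes were higher in them. Leukocyte markers rose, and 7 rose of 7, or 7 up adjusted over the list alone (median 3.10, camera adjusted p = 1.24e-07, adjusted p = 0.215 with an estimated correlation). Ptprc, encoding CD45, was at 328 ± 129.5 against 31.01 ± 16.5 CPM (log2 fold change 3.40, adjusted p = 0.00497). Of the macrophage markers 7 rose of 9, or 9 up adjusted over the list alone (median 2.79, camera adjusted p = 4.74e-08, adjusted p = 0.215 with an estimated correlation). In the class II list 5 rose of 7, or 5 up adjusted over the list alone (median 2.32, camera adjusted p = 1.24e-07, adjusted p = 0.215 with an estimated correlation). H2-Aa was at 5251 ± 1901 against 529.8 ± 343 CPM and Cd74 at 15810 ± 4275 against 1845 ± 823 CPM. Interferon-stimulated genes were higher, and 9 rose of 17, or 13 up adjusted over the list alone (median 1.04, camera adjusted p = 1.38e-08, adjusted p = 0.146 with an estimated correlation). Fibroblast markers were higher, and 6 rose of 10, or 10 up adjusted over the list alone (median 3.15, camera adjusted p = 4.80e-07, adjusted p = 0.239 with an estimated correlation). In the cell cycle list 7 rose of 22, or 11 up adjusted over the list alone (median 1.35, camera adjusted p = 0.000238, adjusted p = 0.392 with an estimated correlation).

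Thyroid differentiation genes were not called as a list, and 2 rose and 1 fell of 16, or 2 up and 1 down adjusted over the list alone (median -0.76, camera adjusted p = 0.491). Pax8 fell (424 ± 226 against 980 ± 299 CPM), Dio2 rose (4.05 ± 2.12 against 0.268 ± 0.0972 CPM) and Slc26a4 rose from 0 counts, at least 21.7-fold. The thyroid score was 5.32 ± 0.32 against 5.91 ± 0.30 (difference -0.60, exact permutation p = 0.1, the smallest possible). Epithelial genes were lower, and 5 fell of 14, or 8 down adjusted over the list alone (median -1.31, camera adjusted p = 0.00405, adjusted p = 0.412 with an estimated correlation). The dissociation stress list was lower, and 4 fell of 13, or 5 down adjusted over the list alone (median -1.14, camera adjusted p = 0.00538, adjusted p = 0.392 with an estimated correlation). Parathyroid markers fell, and 4 fell of 4, or 4 down adjusted over the list alone (median -3.76, camera adjusted p = 0.00405, adjusted p = 0.239 with an estimated correlation). Pth was at 275 ± 209 against 3931 ± 2083 CPM. Beside Smarcb1, Smarca4, Ss18 and Actl6b were lower among SWI/SNF subunits, where 5 fell of 26, or 5 down adjusted over the list alone (median -0.46, camera adjusted p = 0.153). The macrophage, fibroblast and dissociation stress calls were lost with the leukocyte level as a covariate (medians -0.048, 0.43 and -0.12), and the class II median was 1.02. With the stress level the epithelial call was lost (-0.92) and the cell cycle median was 0.89, and without Arid1a knockout library 2 the parathyroid call was lost (-3.67, camera adjusted p = 0.0538).

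The largest rises were mast cell and immune genes: Tpsb2 and Tpsab1, which encode tryptases (0 counts in wild type, at least 1000-fold and 148-fold), the carboxypeptidase gene Cpa3 (1 count, 2020-fold, counting interval 362 to 79800), Cd300e (at least 186-fold) and H2-T3 (at least 173-fold). Among the 5 largest falls were Chga, encoding chromogranin A (116 ± 89.4 against 5569 ± 3417 CPM), and the parathyroid factor gene Gcm2 (0.2598 ± 0.171 against 10.1 ± 6.22 CPM). In all 3538 genes passed, 1301 higher and 2237 lower. Pax8, Pth, Smarcb1, Smarca4, Ss18, Actl6b and Cd300e lost the call without at least 1 library. The count was 1424 without wild-type library 2 and 1610 or 1115 without Arid1a knockout library 1 or 3. In these last and in a fit of only these 6 libraries most calls became higher (890 of 1610, 611 of 1115 and 1474 of 2333). With the leukocyte or the dissociation stress level as a covariate, chosen after these levels were seen, it was 15 or 679.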

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

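The tests of Smarcb1 in Braf Arid1a knockout, of thyroid against epithelial genes and of the thyroid score with the leukocyte level were chosen only after the result was seen, as were the leukocyte and stress covariates.

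Lists whose drug response differed from Braf were found by camera (values: median log2 differences). All 3 comparisons share the Braf libraries and are not independent. With Arid1a loss they included MAPK output (-0.985), cell cycle (-0.906), interferon-stimulated (0.873), dissociation stress (-1.1) and fibroblast genes (2.39), with adjusted p from 0.000124 to 0.0448, and from 0.469 to 0.914 with an estimated correlation. With Arid2 loss they included interferon-stimulated (1.15) and dissociation stress genes (-1.56), with adjusted p = 0.567 and 0.837 with an estimated correlation. With Smarcb1 loss they included thyroid differentiation (-0.551), MAPK output (-1.33), cell cycle (-2.49), interferon-stimulated (2.02), leukocyte (1.81) and fibroblast genes (2.05). With an estimated correlation the interferon list kept its call there (adjusted p = 0.000724), and the others had adjusted p from 0.093 to 0.558. At the preset correlation, calls with Arid1a loss were lost without 1 library for cell cycle (Braf vehicle 2 or 5, Braf CKI 4 or 5, knockout vehicle 3, CKI 4 or 5; -0.82 to -0.27), dissociation stress (knockout CKI 2, -0.60) and fibroblast genes (Braf vehicle 4 or knockout CKI 4, 1.25 and 1.26). The stress median was -0.64 without Braf vehicle 2 and -2.12 without knockout CKI 5 or with the replicate block, where the MAPK median was -1.52. With Arid2 loss the stress call was lost without CKI 3 (-1.401), and without vehicle 4 the stress and interferon medians were -0.997 and 1.755 (0.74 for interferon without vehicle 2). With Smarcb1 loss the thyroid call was lost without Braf vehicle 2 or knockout vehicle 3, with medians from -1.25 to -0.48 over left-out libraries, and the fibroblast call without Braf vehicle 4 (0.77). Covariates ended the MAPK (-0.27, stress level) and cell cycle calls (-0.94, leukocyte level, where the fibroblast median was 1.296) with Arid1a loss and the fibroblast call with Smarcb1 loss (0.55, leukocyte level, where the MAPK median was -0.81). With Arid1a loss the cell cycle call was also lost in a fit of only the compared groups (-0.896), and the median was -1.527 with the stress level.

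Single genes whose response differed with Arid2 loss, as differences in log2 fold change, were Slc26a4 (-6.56), Dio2 (4.61), Dusp6 (-2.26), Spry4 (-2.67), Phlda1 (-2.7), Spred2 (-2.45), Ier2 (-4.93), Jun (-4.48), Junb (-4.08), Isg15 (2.27), Mx2 (2.14), Usp18 (1.85), Tmem135 (-3.84), Zfp692 (-4.06), H2afy2 (-3.35), Schip1 (-3.69) and Fez2 (-3.67). None of them kept the call without each library in turn, and at most 1 gene of any kind was called without CKI library 3 or 4 or with the stress level as a covariate. With Smarcb1 loss they were Slc5a5 (-7.88), Tshr (-2.7), Spry4 (-3.51), Cdc20 (-4.06), Ifit3 (3.01), Usp18 (2.88), Ifit1 (2.83), Irf7 (2.79), Elovl6 (-3.39), Bcl2 (-3.79), Slc26a10 (-4.39), Gstm1 (2.55) and Slc38a1 (-2.18). The first 5, Ifit1 and Irf7 lost the call without at least 1 library. The thyroid score's response differed by -1.24 with Smarcb1 loss and did not pass (permutation p = 0.02, adjusted p = 0.06).

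Smarcb1 was lower in the 3 libraries labelled Arid1a knockout than in wild type. Leukocytes stay open as the whole cause, as their level differed between the groups. With it as covariate Smarcb1 stayed lower (log2 fold change -2.08, interval -3.91 to -0.25). An effect of Arid1a loss that also holds with mutant Braf is argued against by the 0.38 of Braf Arid1a knockout against Braf under vehicle (interval -0.80 to 1.57). Samples from Smarcb1 knockout animals may have been mislabelled, and this stays open: the median change of 162 genes high only in Braf Smarcb1 knockout was 0 (interval 0 to 0.227), in thyroids without mutant Braf. An effect of Arid1a loss in thyroids without mutant Braf also stays open, untested.

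The thyroid differentiation list was higher with CKI in Braf. Fewer non-thyroid cells are argued against as the whole cause, unless CKI lowers epithelial genes. The thyroid median was 2.10 above theirs (interval over genes 0.76 to 4.48). A leukocyte trend as the whole cause stays open, as that level differed between the arms. With it as covariate the thyroid score still differed by 2.32 (SE 0.41, interval 1.46 to 3.19), against 2.43 (SE 0.28) without. Of the 16 genes 5 were then called higher, with a wider SE. An effect of the drug on thyroid cells is the biological explanation the design gives, and it is a hypothesis.

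The MAPK output list was not lower with CKI in Braf. A single library as the cause is argued against, since the lowest median with 1 library left out was 0.16 (0.16 to 0.52). The median was -0.55 (camera adjusted p = 0.0019) with the dissociation stress level as a covariate and -0.43 (camera adjusted p = 0.0328) with the leukocyte level. A trend with either stays open, because both levels differed between the arms. A lack of MAPK inhibition about 2 h after the last dose was not tested.

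Other splits of the same libraries were counted for comparisons of 3 against 3. Splitting 6 libraries gives 10 splits, too few for a share under 0.05, and in each comparison only the real split, 1 of 10, gave as many genes. The real count and the highest other were 2466 and 0 for the drug in Braf, 858 and 0 in Braf Arid1a knockout, 732 and 260 in Braf Smarcb1 knockout, 1818 and 153 for Arid1a loss under vehicle, 5433 and 101 for Smarcb1 loss, 3795 and 2 for Braf against wild type, and 3538 and 0 for Arid1a knockout against wild type. For the differences in response 50 splits of the drug labels were drawn, and they decide nothing about chance. With Arid1a loss the real count was 0 in edgeR (2018 at an unadjusted p under 0.05, 172 in DESeq2), so all 50 had to give as many (highest other 1434). With Smarcb1 loss 5 of 50 gave at least 58, the real one included (highest other 3731). The other 4 each kept the drug labels of a genotype whole, and so hold its drug effect.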

How the results depend on the processing

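The leukocyte, stress and Y-linked covariates were chosen only after those levels were seen, and the other alternatives were planned. Where a count changed, the cause was not tested, except that fits of fewer libraries have fewer samples. A list or gene that makes up a covariate was not recomputed under it.

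With the leukocyte level the counts became 99 for the drug in Braf, 248 in Braf Arid1a knockout, 111 for Arid2 loss and 2373 for Smarcb1 loss under vehicle, 2409 for Braf and 15 for Arid1a knockout against wild type, and 10 for the difference in response with Smarcb1 loss. With the stress level they became 117 (drug in Braf), 991 (Braf Arid2 knockout), 172 (Braf Smarcb1 knockout), 173 (Arid2 loss), 679 (Arid1a knockout against wild type), and 1 and 0 for the differences with Arid1a and Arid2 loss. With the Y-linked share Arid2 loss gave 401.

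Fits of only the compared groups gave 1367, 527, 1651 and 2 for the drug in Braf and the Arid1a, Arid2 and Smarcb1 knockouts, 829, 1 and 2335 for the 3 knockouts against Braf, 2333 for Arid1a knockout against wild type and 5 for the difference with Smarcb1 loss. DESeq2 gave 3917, 1854, 1806 and 1621 for the drug, 2910 and 2120 for Arid1a and Arid2 loss, and 172, 2949 and 268 for the differences. With no filter edgeR called 1 gene in the difference with Arid1a loss.

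The replicate number as a block gave 177 and 339 for the drug in Braf Arid1a and Smarcb1 knockout, 1095 for Arid1a loss and 31 for the difference with Smarcb1 loss. MAPK output and cell cycle medians were then 0.47 and 0.94 in Braf against wild type, MAPK output -1.16 and receptors 0.54 (call lost) for the drug in Braf Arid1a knockout, and leukocytes -2.70 for Smarcb1 loss. Libraries shared only a number: correlations of same-numbered libraries ran from -0.38 to 0.151, and 4 of 6 wild-type and Arid1a knockout libraries correlated best with their own number. RLE size factors kept each count within 1.5 times. The direction with more calls turned in 9 of 14 alternatives for Smarcb1 loss and for the drug in Braf Smarcb1 knockout, 6 of 14 for Braf and 5 of 14 for Arid1a knockout against wild type, 3 of 13 for Arid2 loss, and 1 or 2 for the other comparisons with calls.

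The thyroid list kept its direction in the 4 drug comparisons under each alternative but DESeq2, which was not run on lists. Its adjusted p with an estimated correlation was 0.0723, 0.0836, 0.278 and 0.0925 in the drug comparisons of Braf and the Arid1a, Arid2 and Smarcb1 knockouts, and 0.537 in the difference with Smarcb1 loss. The score differences moved with a pseudocount of 0.1 to 2.93 (Braf) and 2.04 (Arid2 knockout), with 5 to 1.91, 1.61 and 1.52 (Braf, Arid1a and Arid2 knockout), and without Tg to 1.48 (Arid2 knockout).

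Among values called in the fit of all libraries or under the alternative, reversed signs came only with covariates. For the drug in Braf these were MAPK output (-0.55) and cell cycle lists (0.59, camera adjusted p = 0.0404) with stress. With the leukocyte level they were MAPK output (-0.43) and fibroblast lists (1.08, camera adjusted p = 0.0487). Genes with it were H2-Aa (0.069), H2-Eb1 (0.10), C1qa (0.44), C1qb (0.56) and, in Smarcb1 loss, Csf1r (0.42). Macrophage medians of 6 comparisons turned with it too, none called then, as did class II in Braf (0.10) and adipocyte markers in Arid1a knockout (-0.43).

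Leaving out each library gave 726 to 2453, 256 to 756, 65 to 349 and 233 to 923 genes for the drug in the 4 genotypes, 737 to 1637, 38 to 874 and 3889 to 5140 for the knockouts, 2359 to 3809 and 1115 to 4854 against wild type, and 0 to 275, 0 to 2050 and 19 to 77 for the differences. Thyroid list medians ran 1.98 to 2.90, 1.72 to 2.05, 1.66 to 2.21 and 0.57 to 1.61, and -0.35 to 0.05 (not called; above 0 without Braf vehicle 2 or Braf Arid1a knockout CKI 2), -1.01 to -0.36 and -1.25 to -0.48 for the differences. Score differences ran 2.14 to 2.60, 1.79 to 2.25, 1.72 to 1.86 and 0.93 to 1.32, and -0.63 to -0.11, -0.81 to -0.35 and -1.49 to -0.95. Of 530 called values of named genes, 250 kept the call without each library in turn. DESeq2 lost 1, the stress level 180 of 515, the leukocyte level 238 of 513, the compared groups alone 163 of 522, the block 97, no filter 13, RLE 9 and the Y-linked share 49.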

Other observations

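The sex-linked levels were looked at only after the data were seen, and no hypothesis is tested here.

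Markers of other cell types not yet described also differed. In the libraries labelled Arid1a knockout against wild type, T cell markers were higher, and 2 rose of 8, or 4 up adjusted over the list alone (median 2.25, camera adjusted p = 0.00432, adjusted p = 0.392 with an estimated correlation). These were Cd8a and Cd3e, with log2 fold changes of 5.20 and 3.16. Erythroid markers were higher, and 2 rose of 5, or 4 up adjusted over the list alone (median 2.41, camera adjusted p = 0.02403, adjusted p = 0.392 with an estimated correlation). The haemoglobin gene Hbb-b1 (1473 ± 677 against 199.8 ± 132 CPM), which shares reads with its relatives, and Alas2, of haem synthesis (157 ± 50.6 against 23.3 ± 12.1 CPM), rose. Skeletal muscle markers were higher, and 1 rose of 10, or 0 adjusted over the list alone (median 2.08, camera adjusted p = 0.00157, adjusted p = 0.392 with an estimated correlation). The gene called was Atp2a1 (35.2 ± 16.2 against 3.62 ± 4.400 CPM). For adipocyte markers 1 rose of 6, or 1 up adjusted over the list alone (median 2.78, camera adjusted p = 0.0358, adjusted p = 0.392 with an estimated correlation). Cidec had 0 counts in wild type and was at least 28.2-fold higher. The B cell list was not called, and 1 rose of 5, or 1 up adjusted over the list alone (median 1.65, camera adjusted p = 0.129), nor was cartilage and airway, where 1 fell of 6, or 1 down adjusted over the list alone (median -2.08, camera adjusted p = 0.725). Cd22 rose and Foxj1, a factor of ciliated cells, fell. Each gene named here lost the call without at least 1 library. The adipocyte call was lost without wild-type library 1 or knockout library 2 (medians 2.37 and 2.29), with RLE size factors (2.85) and with the Y-linked share (2.33) or stress level (1.825) as a covariate, and the erythroid call without wild-type or knockout library 2 (2.07 and 2.50), and the muscle median was 4.77 without wild-type library 3 and 3.215 with the stress level. With the leukocyte level as a covariate the T cell, erythroid and adipocyte calls were lost (0.053, 1.57 and -0.43) and the muscle median was 1.127.

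Neutrophil markers were lower with CKI in Braf Arid2 knockout (median -3.90, camera adjusted p = 0.00448, adjusted p = 0.278 with an estimated correlation), a median of -3.06 with the member at 0 counts at its bound, though no member passed edgeR's test over all genes and Cxcr2 and S100a8 passed adjusted over the list alone. The call was lost with the leukocyte level as a covariate (-2.695). In Braf, S100a8 fell from 4.94 ± 2.02 to 0.533 ± 0.3802 CPM with CKI, a call lost without at least 1 library, and for this list 2 fell of 6, or 3 down adjusted over the list alone (median -1.80, camera adjusted p = 0.08099).

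Xist and Y-linked genes were both at 10 CPM or more in 13 of 28 libraries. The mean Y-linked share of the sum of these transcripts was 79.9% in wild type and 27.4% in Arid1a knockout. With vehicle and CKI it was 45.9% and 86.5% in Braf, 3.12% and 37.1% in Braf Arid1a knockout, 25.6% and 69.8% in Braf Arid2 knockout, and 64.2% and 90.4% in Braf Smarcb1 knockout.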
